A study of Mus musculus with 8 samples.

How the data were processed

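RNA from 8 samples in 4 groups of 2 (wild type or IRAK4 KI, untreated or acLDL) was measured on Illumina mouse beadchips. The deposited value table holds intensity values on a linear scale that the authors made with BeadStudio, per the submitters' processing notes, whose version is not given in the sources used here. About 29.2% of the values on an array are below 0, and the sorted columns differ by at most 1.4 intensity units, so the values had background subtracted and were quantile normalized, as inferred from the values. Each column's median is 23.7 or 23.8. A second table of signals and detection p-values has 16 columns of per-sample values whose names match no sample label. They were not used in any step.

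The plan made before the data were examined used detection p-values for the background correction and the filter, which needs named columns, so both steps were replaced after the value distribution was seen and before any fit. Intensities were corrected with limma's normexp method (offset 16) and log2 transformed, with no further normalization. Noise was taken as the root mean square of the negative values, 12.2 intensity units. Probes above 3 times the noise on at least 2 arrays were kept, 11819 of 24613. Gene names came from the platform annotation supplied for the probes, where 20984 probes have 1 symbol, 1 has several and 3628 have none. Of these, 20968 entries matched the supplied gene table by gene number, and 0 symbols changed. The labels name the mouseRef-8 v2 chip, while this annotation is that of another platform, and both were joined by probe identifier. Gene names therefore rest on an identifier standing for the same probe on both. Where a gene had several probes, the one with the highest mean over the 8 arrays was used, and unnamed probes stood on their own, giving 10187 items, 8757 of them named.

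All 8 arrays entered one limma fit (version 3.58.1, R 4.3.3) with 4 group means, 5 comparisons, eBayes moderation and Benjamini-Hochberg adjustment over the items of a comparison, with a threshold of 0.05. With 4 residual degrees of freedom the spread is shared between groups. The 5 comparisons share arrays, so their values are not independent of each other. Values are means of log2 intensity with the SD over 2 arrays, and folds are on this scale, which the offset compresses for dim probes. A probe not above noise on either array of a group has only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest value above noise and the probe's own. The 21 gene lists were tested with camera (correlation preset at 0.01, adjusted over the lists of a comparison), with camera's estimated correlation and with fry, which tests whether a list moves on balance one way and does not compare it with other genes. With an estimated correlation camera also takes p from the residual degrees of freedom (4 in this fit) rather than from the number of genes. A call lost in that setting therefore need not be lost to correlation between genes.

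Genes named in the text follow a rule fixed before the data were examined. It takes up to 10 rises and 10 falls of largest size among calls with non-overlapping groups, and from each list up to 4 members past the threshold or, where there is none, up to 2 members with the smallest p. List members are printed for the lists the test called and for lists nearest to the study's question. Other names were chosen after their values were seen, and the text says so. Symbols of unnamed or predicted type gave way to the next named gene, except where the count was 1.

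The procedure was tested on simulated data for the wild type acLDL comparison, with 10187 items and 200 changed genes in each of 5 sets. It called 19.4% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 98.2% of those changed 4-fold, with 6.2 other calls per set. These folds were added on the log2 scale, to noise drawn independently for each gene. The rates thus leave out the compression of dim probes by the offset and any correlation between genes, and hold for 200 changed genes. Alternatives were an offset of 50, no background correction with values under 1 set to 1, median centring, cyclic loess, no filter, a filter on all 8 arrays or at 2 times the noise, every probe on its own, a variance trend, only the groups compared, the replicate number as a block, and leaving out each array in turn. The 2 other filters took the place of planned detection p filters and were chosen after the data were seen. The arrays' slides are not given in the sources used here, so no slide block was fitted. Plots were drawn with matplotlib.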

Results

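Gene expression was measured on 8 Illumina mouse beadchips, 1 biotin-labelled RNA sample per array. The labels describe macrophages grown from mouse bone marrow for 5 days, from wild type mice and from mice with a knock-in that makes the kinase IRAK4 inactive (IRAK4 KI). IRAK4 relays signals from Toll-like and interleukin-1 receptors. Cells were left untreated or given 100 ug/ml acetylated low-density lipoprotein (acLDL), a modified lipoprotein taken up by scavenger receptors, for 24 hours, with 2 arrays in each of 4 groups. The study asked which genes respond to acLDL and how the response differs between genotypes. Nothing in the labels says that the 2 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Each array gave values for 24613 probes, of which between 11026 and 11033 lay above a noise limit of 36.7 intensity units. Correlations across genes between the 2 arrays of a group lay between 0.982 and 0.986, and 3 of 8 arrays had their closest match in their own group. Genes are not independent replicates, so these correlations only describe the arrays.

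The levels of several genes did not match the cell type in the labels, so groups are named below as the arrays labelled so. These genes were chosen after their values were seen. Sftpc and Sftpd, which encode surfactant proteins of the lung, had log2 intensities of 15.19 ± 0.13 and 15.23 ± 0.16 (SD, n = 8). Scgb1a1, a secretoglobin of airway club cells, lay at 14.93 ± 0.09, and Ager, a receptor abundant in alveolar type I cells, at 14.55 ± 0.05 (SD, n = 8). Cldn5, a tight junction gene of endothelium, lay at 14.05 ± 0.15 and Nkx2-1, a transcription factor of lung and thyroid, at 10.61 ± 0.15 (SD, n = 8). Each of the 6 was above noise on all 8 arrays. Of 20 named macrophage identity genes, 10 were above noise on all 8 arrays and 7 on none. Itgam, the integrin chain CD11b, and Fcgr1, an Fc receptor, were above noise on 0 of 8 arrays, while Adgre1, an adhesion receptor gene of macrophages, was above noise on all 8, at 8.92 ± 0.22 (SD, n = 8). Lyz2 and Sirpa, of the same list, were brighter, at 14.46 ± 0.29 and 12.49 ± 0.18 (SD, n = 8). Irak4 itself was not analysed here, because no probe is assigned to it in the probe table used, and a change of kinase activity need not change its transcript. The genotype label was thus not checked on these values, and wild type, KI, untreated and acLDL stand for the labels of the arrays throughout.

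In the arrays labelled wild type, 12 genes were higher and 6 lower with acLDL than without, of 10187 tested. Baiap2l1, which encodes an actin-regulating membrane adaptor, rose 5.33-fold, from a log2 intensity of 7.83 ± 0.14 to 10.24 ± 0.03 (SD, n = 2 each, limma adjusted p = 0.000338). Hsph1, a chaperone of the HSP110 class, rose 5.24-fold from 10.38 ± 0.08 to 12.77 ± 0.27 (SD, n = 2 each, limma adjusted p = 0.00390), and Dnajb1, an HSP40 co-chaperone, rose 4.34-fold (limma adjusted p = 0.0482). Chordc1 (2.74-fold), Ahsa2 (2.66-fold) and Bag3 (2.25-fold), all co-chaperone genes or their relatives, also rose. The other named rises were P4ha1, a collagen prolyl hydroxylase (2.93-fold), Npr3, a natriuretic peptide receptor (2.42-fold), Crem, a cAMP-responsive transcription factor (2.26-fold), and Dusp8, a phosphatase of MAP kinases (1.94-fold). Gfpt2 (1.83-fold) and Naa16 (1.71-fold) also rose and were named after their values were seen. For Crem, 1 of 4 probes was above noise, and for Naa16 1 of 2. S100a8, which encodes a calcium-binding protein of neutrophils, fell by 1.04 on the log2 scale (SE 0.12, limma adjusted p = 0.0300), and Ifi47, an interferon-induced GTPase, fell by 0.92 (SE 0.12, limma adjusted p = 0.0482). The 4 other falls were probes without a gene name here. The count of 18 rested on single arrays: it was 7 and 2 without untreated wild type replicates 1 and 2, 4 and 2 without acLDL wild type replicates 1 and 2, 30 without either untreated KI array and 7 without either acLDL KI array. It was 5 without background correction (5 higher, 0 lower), 6 without a filter (5 and 1) and 10 when only the 4 wild type arrays were fitted (10 and 0).

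**Figure D1:**
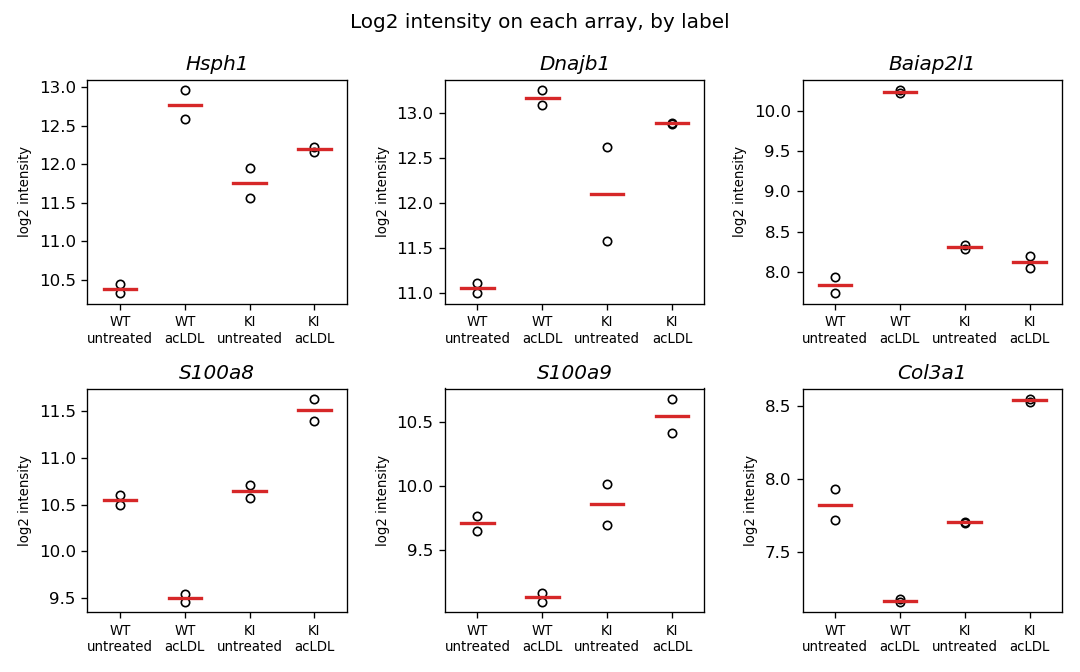
Log2 intensity of 6 genes (vertical axes, each with its own range) on each of the 8 arrays, grouped by label along the horizontal axis. Open circles are arrays and red lines are the means of 2 arrays. Baiap2l1 lies at 10.24 in the wild type acLDL group and between 7.83 and 8.31 in the other groups, and S100a8 falls with acLDL in wild type, from 10.55 to 9.51, and lies at 11.51 in the KI acLDL group.

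Of the 21 lists fixed before the data were examined, 7 shifted down and 1 up in the wild type comparison relative to all other genes (camera, correlation preset at 0.01). None of the 8 was called with an estimated correlation, a setting that also uses fewer degrees of freedom. For lysosomal genes and lymphocyte markers the estimate (0.000969 and -0.0631) lay below the preset. A larger correlation thus does not explain the loss of those calls. Macrophage identity genes had a median log2 change of -0.31, with 12 of 13 measured members lower (camera adjusted p = 0.00187, adjusted p = 0.194 with an estimated correlation). Tyrobp, an adaptor of myeloid receptors, had a log2 change of -0.68 (SE 0.17, limma adjusted p = 0.23) and Aif1 one of -0.55 (SE 0.15, limma adjusted p = 0.24). MHC class II and dendritic cell genes had a median of -0.28, with 13 of 17 lower (adjusted p = 0.000592, adjusted p = 0.354 with an estimated correlation). H2-Oa and H2-DMa, which act in peptide loading, had log2 changes of -0.68 and -0.62 and did not pass the test. Lymphocyte and NK cell markers had a median of -0.26, with 11 of 14 lower (adjusted p = 0.00201, adjusted p = 0.194 with an estimated correlation), and the T cell receptor genes Cd3g and Cd3d had log2 changes of -0.81 and -0.59, neither past the test, though Cd3g passed without either untreated KI array (limma adjusted p = 0.0495). Neutrophil and myeloid progenitor markers had a median of -0.58, with 7 of 9 lower (adjusted p = 0.00715, adjusted p = 0.194 with an estimated correlation). Lysosomal genes had a median of -0.11, with 24 of 32 lower (adjusted p = 0.00715, adjusted p = 0.194 with an estimated correlation), among them the cathepsins Ctss (-0.76) and Ctsk (-0.66), neither past the test. Cell cycle genes had a median of -0.15 with 17 of 20 lower (adjusted p = 0.0140, adjusted p = 0.435 with an estimated correlation). Interferon-stimulated genes were called down with 9 of 17 lower and 8 higher, at a median of -0.06 (adjusted p = 0.0318, adjusted p = 0.435 with an estimated correlation). Unfolded protein and ATF4 response genes were called up, at a median of 0.11 with 17 of 23 higher (adjusted p = 0.0318, adjusted p = 0.243 with an estimated correlation). Their members Herpud1 and Ddit3 had log2 changes of 0.75 and 0.73, neither past the test over all genes. On leaving out 1 array some of these calls were lost. The adjusted p was 0.0531, 0.0723 and 0.210 for the interferon list (medians -0.02, -0.05 and -0.13) and 0.0722, 0.0714 and 0.285 for the unfolded protein list (medians 0.07, 0.08 and 0.05) without untreated wild type replicate 1, untreated wild type replicate 2 and acLDL wild type replicate 2. It was 0.226 and 0.141 for the cell cycle list (medians -0.12 and -0.11) without untreated wild type replicate 2 and acLDL wild type replicate 1, and 0.210 for the neutrophil list (median -0.27) without acLDL wild type replicate 2. Without a filter the interferon list had a median of 0.00113 (adjusted p = 0.0622), and the unfolded protein list had an adjusted p of 0.0622 without a filter and 0.106 among genes above noise on all 8 arrays. Counted over all lists and adjusted over the list alone, 4 members were higher and 21 lower.

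Lists nearer to lipid loading and to IRAK4 were not called in wild type. LXR target genes, which respond to oxysterols, had a median log2 change of -0.09 over 11 genes (camera adjusted p = 0.263), and Abcg1, a cholesterol exporter, had one of -0.26 (SE 0.18, limma adjusted p = 0.62). Cholesterol synthesis genes had a median of -0.04 over 19 genes (adjusted p = 0.523). Scavenger receptor and lipid storage genes had a median of 0.11 over 24 genes (adjusted p = 0.154), and their member Angptl4, a lipase inhibitor, had a log2 change of 1.76 (SE 0.44, limma adjusted p = 0.23, or 0.0333 without either untreated KI array). Inflammatory cytokines (median -0.15 over 20 genes, adjusted p = 0.161), NF-kB components (-0.11 over 19, adjusted p = 0.263) and Toll-like and interleukin-1 receptor components (-0.11 over 25, adjusted p = 0.0629) did not pass either. Adjusted over the list alone, 3 Toll-like and interleukin-1 receptor components were lower and 0 higher. By the same measure 1 NF-kB component was higher and 2 were lower, and 0 cytokine genes changed. Ier3, an immediate early gene, and Tlr2 had log2 changes of -0.73 (SE 0.14) and -0.64 (SE 0.13), with limma adjusted p of 0.16 and 0.17.

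In the arrays labelled IRAK4 KI, 2 probes were higher with acLDL and 0 lower. One belongs to Tm7sf3, a membrane protein gene, and was above noise in the KI acLDL arrays and in no other group. It was at least 2.24-fold higher there (limma adjusted p = 0.00234), while the other 2 probes of the gene were above noise on no array. The other called probe has no gene name here and was at least 3.32-fold higher (limma adjusted p = 0.00234). S100a8, with a log2 change of 0.87 (SE 0.12, limma adjusted p = 0.15), and Col3a1, a fibrillar collagen, with 0.83 (SE 0.11, limma adjusted p = 0.090), did not pass. Interferon-stimulated genes were called up, with 15 of 17 higher at a median of 0.22 (camera adjusted p = 0.000260, adjusted p = 0.593 with an estimated correlation). Rsad2, an antiviral gene, had a log2 change of 1.91 (SE 0.40, limma adjusted p = 0.52, or 0.0300 without either wild type acLDL array). Cell cycle genes were called up with 15 of 20 higher at a median of 0.19 (adjusted p = 0.0370, adjusted p = 0.593 with an estimated correlation). The cell cycle call was lost without untreated KI replicate 1 (median 0.20, adjusted p = 0.0581), untreated KI replicate 2 (0.13, adjusted p = 0.131) and acLDL KI replicate 2, where the median turned to -0.07 (adjusted p = 0.991). It was also lost without background correction (adjusted p = 0.0944) and among genes above noise on all 8 arrays (adjusted p = 0.0806). The interferon call was lost without acLDL KI replicate 2 (median 0.09, adjusted p = 0.211). The count of 2 was 0 without untreated KI replicate 2 and 6 without either wild type acLDL array. It was 1 without background correction or without a filter, and 0 among genes above noise on all 8 arrays.

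**Figure D2:**
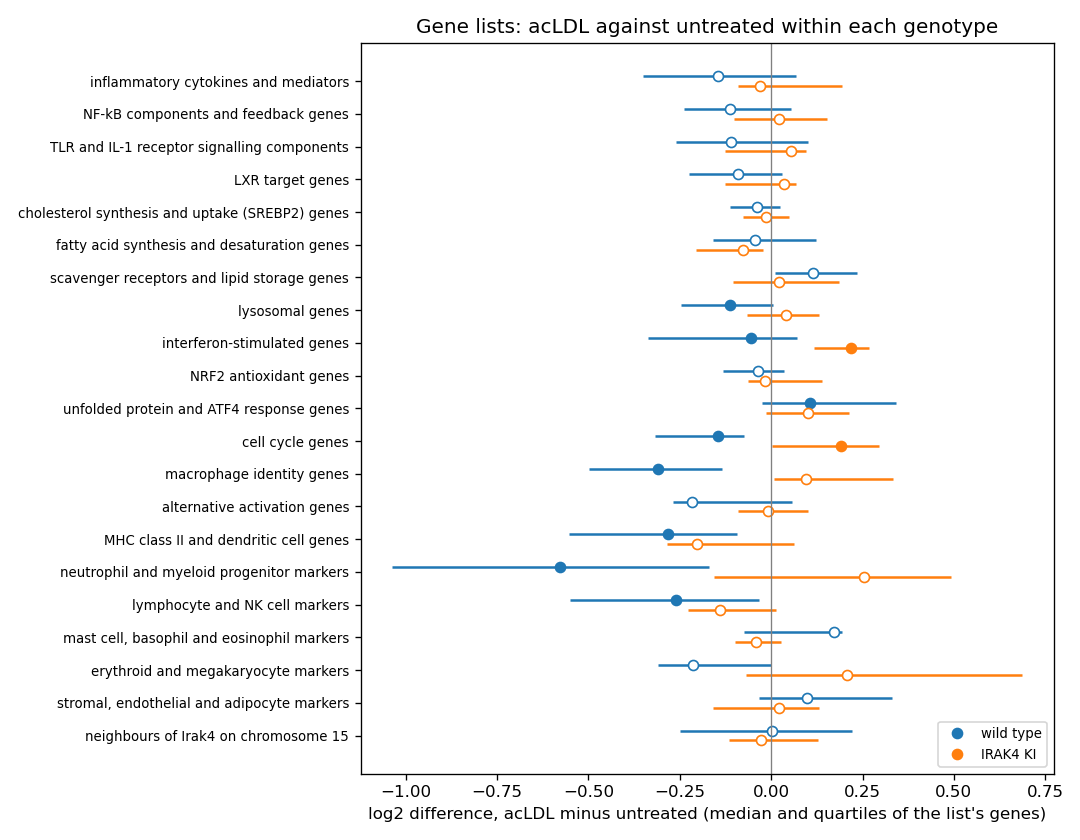
Median log2 difference, acLDL minus untreated (horizontal axis), of the measured genes of 21 gene lists (vertical axis), in wild type (blue) and IRAK4 KI (orange). Lines span the quartiles and filled points are lists called by camera with the preset correlation. With the preset correlation 8 lists are called in wild type and 2 in IRAK4 KI, and with an estimated correlation 0 in either.

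The acLDL effects of the 2 genotypes were then tested against each other. They differed for 5 probes, 4 with a more positive effect in KI and 1 with a more negative one. The log2 effect on Baiap2l1 was 2.59 lower in KI than in wild type (difference -2.59, SE 0.16, limma adjusted p = 0.00281), and in KI its level was 8.31 ± 0.03 without and 8.13 ± 0.10 with acLDL (SD, n = 2 each). The effect on S100a8 was 1.90 higher in KI (SE 0.17, limma adjusted p = 0.0174) and that on Col3a1 1.48 higher (SE 0.15, limma adjusted p = 0.0276), the latter from 1 probe, while the other probe of the gene was above noise on 1 array. The S100a8 call was lost without any single array other than acLDL KI replicate 1 (limma adjusted p = 0.0578 to 0.162), and the Col3a1 call without any single one of the 8 (limma adjusted p = 0.0560 to 0.203). Tm7sf3 and the unnamed probe made up the rest, both near background outside the KI acLDL arrays. Lists called up in this test were neutrophil and myeloid progenitor markers (median difference 0.83, 8 of 9 higher, camera adjusted p = 0.00128), interferon-stimulated genes (0.39, 16 of 17, adjusted p = 4.4e-05), macrophage identity genes (0.38, 11 of 13, adjusted p = 0.00101), cell cycle genes (0.27, 17 of 20, adjusted p = 0.000464) and lysosomal genes (0.12, 23 of 32, adjusted p = 0.00397). With an estimated correlation, adjusted p was 0.231 for the neutrophil, macrophage and lysosomal lists, 0.303 for the interferon list and 0.326 for the cell cycle list. The cell cycle call was lost without acLDL KI replicate 2 (median 0.16, adjusted p = 0.0805) and the neutrophil call without acLDL wild type replicate 2 (median 0.25, adjusted p = 0.0599). Across all tested genes, which are not independent replicates, the acLDL effects correlated at r = 0.17, and 11 of the 18 genes called in wild type had the same sign in KI, with a median ratio of the KI effect to the wild type effect of 0.19. Among the 15 of these above noise on all 8 arrays, a restriction chosen after the data were seen, 11 had the same sign and the median ratio was 0.20. Genes chosen for a call in one genotype overstate the effect there, which lowers the ratio, and 51.1% of all tested genes had the same sign. The reverse ratio is not given, because 0 of the 2 probes called in KI were above noise on a wild type array. The count of 5 was 1 without untreated wild type replicate 1, acLDL wild type replicate 2, either untreated KI array or acLDL KI replicate 2, and 3 without acLDL KI replicate 1. It was 2 without background correction (1 more positive, 1 more negative in KI), 3 without a filter (2 and 1) and 6 with an offset of 50 (4 and 2).

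Between untreated arrays, 1 gene differed between the genotypes. The gene 1700029J07Rik had a log2 intensity of 8.91 ± 0.01 in wild type and 7.02 ± 0.19 in KI (SD, n = 2 each, 3.69-fold lower, limma adjusted p = 0.0306). At an unadjusted p under 0.05, 1524 genes differed, against 509 expected on average if no gene differed. Genes that vary together can take such a count far from that average, so it does not measure a genotype effect. The other comparisons exceeded 509 too, with 1225 for acLDL in wild type, 658 in KI, 875 for the difference and 2218 between acLDL arrays. Fatty acid synthesis genes were higher in KI for 14 of 14 members, at a median of 0.20 (camera adjusted p = 0.00844, adjusted p = 0.662 with an estimated correlation), with Agpat2, an acyltransferase, at 0.88 (SE 0.26) and Thrsp, a lipogenic regulator, at 1.81 (SE 0.57), neither past the test over all genes. Stromal, endothelial and adipocyte markers were higher for 14 of 16, at a median of 0.26 (adjusted p = 0.00864, adjusted p = 0.662 with an estimated correlation), and Adipoq, a hormone of fat cells, had a log2 difference of 2.69 (SE 0.63, limma adjusted p = 0.20). Whether the share of fat cells differed between these arrays was not tested. It would bear on the fatty acid list as well, so neither list call can be ascribed to the knock-in. The genes that neighbour Irak4 on chromosome 15 had a median of -0.02 over 22 genes (adjusted p = 0.873), and Vdr, the vitamin D receptor gene, had a difference of -0.65 (SE 0.17, limma adjusted p = 0.21). The fatty acid call was lost without untreated wild type replicate 2 (median 0.21, adjusted p = 0.0838). The stromal call was lost without untreated wild type replicate 1 (median 0.16, adjusted p = 0.0780), without untreated KI replicate 1 (0.19, adjusted p = 0.130), without a filter (0.16, adjusted p = 0.0990) and among genes above noise on all 8 arrays (0.23, adjusted p = 0.0716). The call of 1700029J07Rik was lost in 6 of the 8 fits that left out 1 array: limma adjusted p was 0.206 and 0.149 without untreated wild type replicates 1 and 2, 0.0808 without either acLDL wild type array, and 0.0601 and 0.245 without untreated KI replicates 1 and 2. Without untreated wild type replicate 2 the count was still 1, with 0 shared, and in the 5 others it was 0. It was also 0 without background correction, without a filter and when only the 4 untreated arrays were fitted.

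Between acLDL arrays, 16 genes or probes were higher and 6 lower in KI than in wild type, a split that depended on the setting: 32 were higher and 21 lower with an offset of 50, 32 and 29 among genes above noise on all 8 arrays, and 8 and 8 without acLDL KI replicate 1. S100a8 was 3.99-fold higher (limma adjusted p = 0.000834) and S100a9, its partner protein, 2.66-fold higher, from 9.13 ± 0.05 to 10.54 ± 0.20 (SD, n = 2 each, limma adjusted p = 0.0154). Col3a1 (2.58-fold), Parp12, an interferon-induced ADP-ribosyltransferase (2.20-fold), Ifi47 (1.96-fold) and Ogn, a matrix proteoglycan (1.81-fold), were higher as well. For Ogn the other probe, also above noise, had a log2 difference of 0.10. Tm7sf3 was at least 2.23-fold and Trim10, a gene of red cell development, at least 1.32-fold higher, each from 1 probe measured in the KI acLDL arrays alone. Lower in KI were Baiap2l1 (4.34-fold), the proteasome subunit gene Psmb1 (2.86-fold), the sphingomyelin synthase gene Sgms1 (2.68-fold), Gprc5a, an orphan receptor (2.19-fold), Sh3tc2 (1.84-fold) and Dcaf5 (1.78-fold). The other 8 were probes without a gene name here. Psmb1 and Sgms1 had lower values in KI between the untreated arrays too, with log2 differences of -0.80 and -0.67, not past the threshold there. Their difference is thus not particular to the acLDL arrays. The untreated difference was 0.47 for Baiap2l1, -0.25 for Gprc5a, -0.12 for Sh3tc2 and -0.22 for Dcaf5. Interferon-stimulated genes were called up with 15 of 17 higher at a median of 0.33 (camera adjusted p = 1.7e-05, adjusted p = 0.455 with an estimated correlation), cell cycle genes with 19 of 20 higher at 0.35 (adjusted p = 0.000251, adjusted p = 0.455 with an estimated correlation), and macrophage identity genes with 11 of 13 higher at 0.42 (adjusted p = 0.0192, adjusted p = 0.455 with an estimated correlation). Tyrobp had a log2 difference of 0.94 (SE 0.17) and Spi1, the myeloid regulator PU.1, one of 0.56 (SE 0.11), with limma adjusted p of 0.076 and 0.080. Adjusted over the list alone, 27 members over all lists were higher and 11 lower. The cell cycle call was lost without acLDL KI replicate 2 (median 0.08, adjusted p = 0.0549), and the macrophage call without acLDL wild type replicate 2 (0.36, adjusted p = 0.194) and acLDL KI replicate 1 (0.33, adjusted p = 0.0696). The genes that neighbour Irak4 had a median of -0.08 (camera adjusted p = 0.888). Adjusted over this list alone, 1 of its 22 members was higher and 3 were lower in KI, changes in both directions that a median does not show. The share of genes outside a list that would pass such an adjustment was not computed, for this list or the others. By a looser measure, an unadjusted p under 0.05 in limma, 2218 of all 10187 items differed in this comparison. The counts therefore do not set these neighbours apart from other genes. The count of 22 was 13 without either untreated wild type array (12 higher, 1 lower), 12 without either untreated KI array (11 and 1), and 4 without acLDL wild type replicate 2 or acLDL KI replicate 2. It was 5 without background correction, 8 without a filter and 7 when only the 4 acLDL arrays were fitted, and rose to 53 with an offset of 50, 59 with a variance trend and 61 among genes above noise on all 8 arrays.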

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

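The test of leukocyte genes below was chosen after the list results were seen, and the test of a trend with expression level before its value was seen. The effect of acLDL differed between the genotypes in a test of the difference itself for 5 probes and 5 gene lists. In log2 units, KI minus wild type, the difference was -2.59 for Baiap2l1, 1.90 for S100a8 and 1.48 for Col3a1. For Tm7sf3 and the unnamed probe ILMN_2696696 the fitted values were 2.17 and 1.94, which are not sizes, because they set 2 arrays above noise against 6 that were not. Within KI the 2 probes were at least 2.24-fold and 3.32-fold higher with acLDL. The difference passed the threshold in 18 of 18 other settings for Baiap2l1, 9 of 18 for S100a8 and 7 of 18 for Col3a1. It was lost for S100a8 without any single array other than acLDL KI replicate 1 (limma adjusted p = 0.0578 to 0.162), for Col3a1 without any single array (0.0560 to 0.203), and for Tm7sf3 and the unnamed probe in 7 of 8 such fits each, all but those without untreated wild type replicate 2 and acLDL wild type replicate 1 (0.0747 to 0.203 and 0.0578 to 0.162). The median difference was 0.83 for neutrophil and myeloid progenitor markers, 0.39 for interferon-stimulated genes, 0.38 for macrophage identity genes, 0.27 for cell cycle genes and 0.12 for lysosomal genes. None of the 5 lists was called with an estimated correlation, where adjusted p lay between 0.231 and 0.326. With the preset correlation, the neutrophil call was lost without acLDL wild type replicate 2 (median 0.25, adjusted p = 0.0599) and the cell cycle call without acLDL KI replicate 2 (0.16, adjusted p = 0.0805).

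Macrophage, MHC class II, lymphocyte and neutrophil lists were called lower in the arrays labelled wild type acLDL than in untreated wild type arrays with the preset correlation, with a median log2 change of -0.31 over 53 measured genes. None of the 4 was called with an estimated correlation (adjusted p = 0.354 for MHC class II and 0.194 for the others), and the neutrophil call was lost without acLDL wild type replicate 2 (median -0.27, adjusted p = 0.210). A trend with expression level is argued against: random lists matched on mean expression had a median that was -0.0277 of that change. A lower share of leukocytes in these samples may account for it: 18 of 18 measured genes of a list shared by all leukocytes, none of them in a list fixed before, were lower, at a median of -0.37 (camera with an estimated correlation, unadjusted p = 0.00276, adjusted p = 0.0498 over the 18 tests of lists chosen after the data were seen), and 0% of 10000 matched random lists had a median as low. The list had lower values with acLDL in KI too, for 14 of 18 genes at a median of -0.14 (adjusted p = 0.199 with an estimated correlation), and lower in untreated KI than in untreated wild type arrays for 14 of 18 at -0.16 (adjusted p = 0.144), neither past the threshold, and the difference of the acLDL effects had a median of 0.26 (adjusted p = 0.0985). Between the acLDL arrays 10 of its genes were higher and 8 lower in KI, at a median of 0.08 (adjusted p = 0.267 with an estimated correlation). With 2 arrays against 2 this list did not pass the correction on leaving out any 1 of the 8 arrays (wild type median -0.37 to -0.29, adjusted p = 0.104 to 0.242), and a response of leukocytes to acLDL stays open, as the design does not separate it from a change in cell share.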

How the results depend on the processing

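The filters at 3 times the noise on all 8 arrays and at 2 times the noise were chosen after the data were seen. Counts of called genes depended on the settings, and where the construction does not show why, the cause was not tested. In wild type the acLDL count of 18 was 5 without background correction, 6 without a filter, 10 with only the groups compared and 2 to 30 on leaving out 1 array. In KI the count of 2 was 1 without background correction, without a filter or at 2 times the noise, 0 with the filter on all 8 arrays, which removes both called probes, and 0 to 6 on leaving out 1 array. The count of 5 for the difference was 2 without background correction, 3 without a filter and 1 to 4 on leaving out 1 array. The untreated count of 1 was 0 without background correction, without a filter and with only the groups compared, and 0 to 1 on leaving out 1 array. The acLDL count of 22 between genotypes was 53 with an offset of 50, 5 without background correction, 8 without a filter, 61 with the filter on all 8 arrays, 59 with a variance trend, 7 with only the groups compared and 4 to 16 on leaving out 1 array. Of 105 list tests 20 were called, against 0 with an estimated correlation and 1 with fry (lymphocyte and NK cell markers in wild type), and 16 to 25 on leaving out 1 array. The correlation of acLDL effects across genes, 0.17, was 0.0955 without a filter and 0.0421 to 0.224 on leaving out 1 array. Of 48 gene or probe calls, 4 passed in every setting (Baiap2l1 in 3 comparisons and S100a8 between the acLDL groups), Tm7sf3 between the acLDL groups passed in the 16 settings that used its called probe, which the other 3 filters did not, and 42 were lost on leaving out at least 1 array, with 0 reversed. Of 20 list calls, 8 passed in every setting that kept the preset correlation. Named genes not past the threshold passed it in 13 fits: Angptl4 and Cd3g in wild type without either untreated KI array, Rsad2 and Slc4a1 in KI without either wild type acLDL array, and between the acLDL groups Hspa5, Ppp1r15a and Slc4a1 with the filter on all 8 arrays, Ppp1r15a without KI acLDL replicate 1 and Slc4a1 without wild type acLDL replicate 1. Others, 2 in number, changed sign in KI: Ctss to -0.00481 without KI untreated replicate 1 (0.640 without replicate 2) and Gata2 to -0.0234 without KI acLDL replicate 1.

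Arrays of different groups share replicate numbers, and the labels do not say that a number marks a shared animal or day. Deviations of same-numbered arrays correlated between -0.31 and 0.29 over the 6 pairs of groups, above 0.1 in 3, so the numbers were not taken as pairs. Those 3 were the pairs without untreated wild type (0.19 to 0.29), and all pairs with it were negative (-0.31 to -0.06). Variation shared across groups under other numbers is therefore not excluded. Replicates 1 of untreated and acLDL KI correlated at 0.991, above any pair within a group (at most 0.986). The source of this was not tested. With the replicate number as a block the counts were 7, 2, 1, 0 and 16 for wild type, KI, the difference, untreated and acLDL arrays, and 21 list tests were called. The scanner table, a slide block and the level of Irak4 were listed before the data were examined and were not run.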

Other observations

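Of the tests in this part, those on macrophage genes, row identifiers and cilia genes, the heat shock list, the genotype fit over both treatments and the clock and Y-linked genes were chosen after values were seen. Heat shock chaperone genes, 18 of which were measured, were higher with acLDL in wild type for 17 members, at a median log2 change of 0.82 (camera with an estimated correlation, unadjusted p = 0.0142, adjusted p = 0.0985 over the 18 tests of 3 lists chosen after the data were seen), and 5 members were called. The list thus did not pass the correction. Its 5 called members are Hsph1, Dnajb1, Chordc1, Ahsa2 and Bag3, the wild type calls described above. The list result is therefore not separate support for those calls, and the remaining members were not tested on their own. In KI 18 of 18 were higher, at a median of 0.32 (adjusted p = 0.144 with an estimated correlation), which was 0.15 with 16 higher without untreated KI replicate 1. The difference of the effects had a median of -0.55 (adjusted p = 0.144 with an estimated correlation). Untreated KI arrays already lay above untreated wild type arrays for 15 of 18, at a median of 0.56 (adjusted p = 0.144 with an estimated correlation, median 0.37 without untreated KI replicate 2), and differed from each other, with Dnajb1 at 11.57 in replicate 1 and 12.62 in replicate 2.

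A fit of genotype and treatment over all 8 arrays called 365 genes for genotype, 132 higher and 233 lower in KI, and 0 for treatment (limma, 934 at an unadjusted p under 0.05). The genotype count was 0 without either untreated wild type array, acLDL wild type replicate 1, either untreated KI array or acLDL KI replicate 1, 1 without acLDL KI replicate 2 and 550 without acLDL wild type replicate 2. Genotype alone called 119 genes, against at most 1 in the other splits of the arrays into 4 and 4, so that 1 of 35 splits gave as many. This speaks against a random grouping only if the 2 arrays of a group are independent samples, which the labels do not say. Otherwise the 3 splits that keep each group whole are too few for a share under 0.05; the other 2 of them gave 0. Motile cilia genes were lower in KI for 95.5% of the 22 measured, 5 of them called, among them Rsph4a, a radial spoke gene, at 8.92 ± 0.32 in wild type and 8.11 ± 0.32 in KI (SD, n = 4 each, limma adjusted p = 0.0450). A lower share of ciliated cells in the KI samples is a possible explanation, and 0% of 10000 matched random lists had a median as low as -0.28, but with an estimated correlation the list's unadjusted p was 0.138 and its adjusted p 0.267. The list was also lower with acLDL in KI, for 20 of 22 genes at a median of -0.26 (adjusted p = 0.267 with an estimated correlation), and in wild type for 14 of 22 at -0.10 (adjusted p = 0.651). Both medians rested on single arrays: that in KI was -0.09 without acLDL KI replicate 2 (15 of 22 lower), -0.16 without untreated KI replicate 1 and -0.39 without acLDL KI replicate 1, and that in wild type -0.16, -0.00559 and -0.05 without untreated wild type replicates 1 and 2 and acLDL wild type replicate 2. Whether cell share, genotype or treatment underlies the pattern stays open.

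The high levels of genes typical of lung on every array argue against macrophages as the main source of the RNA. The macrophage genes do not decide it. Of 20 named macrophage identity genes 50% were above noise on all 8 arrays, and random lists of 16 named genes had a median of 8. The chaperone genes Hsp90aa1 and Dnaja1 were above noise on 0 arrays too, at 5.38 and 5.94. Whether a probe below noise means an absent transcript was not tested. Of 16 named genes of a further lung list, whose values had not been looked at, 93.8% were above noise on all 8 arrays, against at most 60% for 9 lists of other tissues (heart), and they include Cav1 at 13.16 ± 0.13 and Cldn18 at 12.59 ± 0.11 (SD, n = 8). Probe identifiers out of register are argued against, as 0.0400% of lists had as many genes above noise, with the further lung list counted in beside 10000 random gene lists. An earlier test, whether 2 probes of one gene were above noise together, gave a kappa of 0.207, between the bounds of 0.1 and 0.3 set for it. If the group labels hold, the treatment or the knock-in does not account for the pattern, as 100% of the 16 were above noise on both arrays labelled untreated wild type, and lung tissue as the source of the RNA is a hypothesis consistent with these values. If the values belong to other samples than the labels describe, the genotype and treatment labels may not apply to them either, which was not tested and would bear on every comparison.

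The shares for the other lists were 12.5% for liver, 10% for kidney, 27.3% for brain, 25% for skeletal muscle, 10% for intestine, 0% for testis, 12.5% for pancreas and 14.3% for skin. A share over all 8 arrays does not show signal on single arrays. Of 8 named skeletal muscle genes, 1 was above noise on no array. Acta1 ranged from 5.06 to 13.23 and Pvalb from 4.99 to 11.17, each above noise on 2 arrays. Tnni2 (6.96 to 11.56) and Tnnt3 (6.06 to 10.36) varied widely as well, and Actn3 less (6.38 to 7.98). Of heart genes, Myl7 ranged from 8.41 to 11.22 and Mybpc3 from 6.47 to 6.91. The lung genes Ager and Cldn18 ranged only from 14.48 to 14.62 and from 12.39 to 12.74. Muscle transcripts thus differed between arrays far more than these lung transcripts. Whether this tissue make-up followed the groups was not tested, and it would bear on the comparisons. The labels give female mice. Of 3 Y-linked genes with a probe, Eif2s3y was above noise on all 8 arrays, Kdm5d on 3 and Uty on 0, and binding of the Eif2s3y probe to the transcript of its X-linked relative was not tested. In KI acLDL replicate 2 the clock genes Dbp, Tef, Nr1d1 and Cry2 lay at 7.85, 11.34, 6.82 and 8.45, against 10.77, 12.54, 8.34 and 8.79 in replicate 1. Arntl, Nr1d2 and Clock lay at 7.95, 7.36 and 10.86, against 6.82, 7.02 and 10.57. Per3 was above noise on 3 of the 8 arrays and not on this one.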
